A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

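Gene expression was measured by RNA sequencing in 12 libraries of the yeast Saccharomyces cerevisiae, with 4 genotype groups of 3 biological replicates. The strains were MATα and of the W303 background, and cells were grown in synthetic complete medium at 24 °C to mid-log phase, per the labels' protocols. RNA was extracted with hot phenol, treated with DNase and depleted of rRNA before strand-specific total RNA libraries were made, per the labels' protocols. The groups were taken from the labels: wild type, epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ. The genotype names in the text are those of the labels.

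The deposited values were RPKM (reads divided by gene length and by the library's reads), with 1 value per gene or RNA and 7126 features in each library. The submitters' processing notes name cutadapt, Bowtie 0.12.2 and STAR and the genome builds sacCer3 and mm8, without saying what each was used for. The counting program, its strand setting and its treatment of reads that match several places are not stated in the labels. Values of overlapping genes, antisense genes and near-identical gene copies are therefore uncertain. The authors' values were checked for whole reads by multiplying each RPKM by the annotated gene length. Between 99.7111% and 99.7465% of the values checked in a library, those under 5000 reads, were whole multiples of 1 step within 0.01 read. Read numbers were recovered from these steps, and the reads behind a library's RPKM ranged from 8089179 to 14527280. At that depth, 1 read in a gene of 1 kb was worth between 0.0688 and 0.124 RPKM.

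Names, positions and lengths came from the SGD annotation, release R64-5-1, of the R64 genome, which is the same assembly as sacCer3. Locus tags matched 6048 features and names matched 114 RNA genes. The 964 features without a match were 688 open reading frames and 276 tRNA names. Those that passed the expression filter were tested without a position. Of all features, matched or not, 321 were at 0 in all 12 libraries. The 14 nuclear rRNA features were all among these and were left out.

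The main test used R 4.3.3 with limma 3.58.1. RPKM values were divided by median-of-ratios scaling factors, which ranged from 1.02 to 1.22 in the wild-type libraries and from 0.914 to 1.01 in the others. Features with a mean of at least 1 RPKM over the 12 libraries were tested, which left 5956. The test was run on log2(scaled RPKM + 1) with 1 mean per group, all 12 libraries in 1 fit and empirical Bayes moderation with a mean-variance trend. Fold changes are differences on this log2(RPKM + 1) scale, which understates the change of low genes. P-values, for changes in either direction, were adjusted by the Benjamini-Hochberg method within a comparison. A gene was called changed at an adjusted p under 0.05, and "rose" and "fell" are used for such calls alone. The 6 comparisons were each mutant label against wild type and each pair of mutant labels. The main test had no block for the replicate number. Deviations from the group means were correlated above 0.1 in all 3 same-numbered pairs of wild type and esa1Δ sds3Δ (0.124, 0.125 and 0.182), and in no other comparison were all 3. The numbers were therefore taken to pair the libraries in that comparison, from the values alone, since the labels name no shared day or batch. Its values with the number as a block are given where they change a call.

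Of 39 gene lists written beforehand, the 38 with at least 4 tested members were tested with camera, limma's competitive gene set test. Its preset inter-gene correlation of 0.01 was used, with Benjamini-Hochberg adjustment over the lists of a comparison. The camera tests were repeated with a correlation estimated from the residuals. Counts of changed members are given over all tested genes and adjusted over the list alone. The subtelomeric list held the protein-coding genes that lie whole within 20 kb of a chromosome end.

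The genes named were also chosen by a rule set beforehand. EPL1, ESA1 and SDS3 came first, in every library, with the nearest annotated gene on either side and the auxotrophic marker genes. Up to 10 genes per direction were named with the largest fold change among those with an adjusted p under 0.05, a mean of at least 10 RPKM in the higher group, and every library of one group beyond every library of the other. For each gene list, up to 4 members with the smallest adjusted p were named, and any members needed to say which did not pass. HMRA1 and HMRA2, the genes of a silent mating-type cassette, were named as intended readouts of silencing.

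Overlaps and correlations between comparisons that share the wild-type libraries were set beside 100 simulations of unchanged groups. In these, all 12 libraries were drawn anew, wild type included, and the simulated wild type was shared. For each comparison, all 10 splits of the 6 libraries into equal groups were tested. The limma and camera steps were tested on simulated data before use. The simulated genes varied independently, on values already scaled and filtered. Scaling, the filter and correlation between genes were therefore not tested. In a simulation of the epl1Δ sds3Δ against wild-type comparison with 5956 genes, 200 of them changed, limma recovered 62% of genes raised by 0.5 on the log2 scale, 88% of those raised by 1, 86% of those lowered by 1 and 100% of those raised by 2. There were 5 false calls, 2.89% of all calls. A simulated list of 30 raised genes gave a camera p of 6.42e-41, and a list of 30 unchanged genes gave 0.191.

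The test, the lists, the naming rule and most alternatives were chosen before the data were examined. These alternatives were RPKM as deposited, quantile normalization, a pseudocount of 0.1 or 5, no filter or a mean of at least 10 RPKM, a fit of only the groups compared, a replicate block, moderation without trend, library weights and leaving out each library in turn. For the lists they also included the estimated correlation, and for the subtelomeric list distances of 10 and 40 kb. Limma voom on the recovered reads, and RPKM after thinning all libraries to the depth of the shallowest, were added after the data had been seen. Other steps used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. A search for shared sequence between genes used stretches of 50 bases.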

Results

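RNA sequencing of rRNA-depleted total RNA was used to compare wild-type yeast with strains lacking essential subunits of the NuA4 histone acetyltransferase. ESA1 encodes the catalytic subunit of NuA4 and of the smaller piccolo-NuA4 complex, and EPL1 encodes a subunit of both. SDS3 encodes a subunit of the Rpd3L histone deacetylase, and its loss allows cells without ESA1 or EPL1 to live. The libraries were labelled wild type, epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ, with 3 biological replicates each and 12 libraries in all. No libraries labelled sds3Δ alone were included, so the share of a change that comes from its loss cannot be separated. The reads behind the RPKM values numbered 13071781 to 14390732 in the wild-type libraries and 8089179 to 10314855 in the libraries labelled epl1Δ sds3Δ. They numbered 8897111 to 8917129 in those labelled esa1Δ sds3Δ. In those labelled esa1Δ epl1Δ sds3Δ, replicates 1, 2 and 3 had 9046732, 8378148 and 14527280. Protein-coding genes took 67.3% ± 0.713 of the reads in wild type and 57.4% ± 1.22, 58.4% ± 0.791 and 56.2% ± 1.05 in the groups labelled epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ (SD, n = 3 each). Small nucleolar RNAs (snoRNAs) took 16.3% ± 0.434 in wild type and 26.1% ± 0.279, 26.7% ± 1.05 and 27.4% ± 0.652 in the same order. The signal recognition particle RNA SCR1 took between 16.2% ± 0.145 in wild type and 17.7% ± 1.13. Within each group, the lowest correlation between replicates across genes lay between 0.984 and 0.991.

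The genes named as deleted were examined first, in every library, as a check of the labels. ESA1 (YOR244W, XV 792531 to 793868 in R64) had 256, 181 and 310 reads in the wild-type libraries, between 1 and 3 reads in the 6 libraries labelled esa1Δ, and 228, 188 and 158 in those labelled epl1Δ sds3Δ. EPL1 (YFL024C, VI 87847 to 90345) had 142, 73 and 130 reads in wild type, 5, 4 and 4 in the libraries labelled epl1Δ sds3Δ, 13, 8 and 10 in those labelled esa1Δ epl1Δ sds3Δ, and 106, 62 and 68 in those labelled esa1Δ sds3Δ. Both genes followed their labels. SDS3 (YIL084C, IX 202276 to 203259) had 142, 112 and 158 reads in wild type and did not go to near 0 in any library labelled sds3Δ, where it had between 36 and 77 reads. This goes against the sds3Δ label, so groups are named here by their labels. The mean scaled level of SDS3 was 8.93 ± 0.421 RPKM in wild type and 5.26 ± 0.402, 5.66 ± 0.897 and 5.83 ± 1.95 in the libraries labelled epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ (SD, n = 3 each), or 58.9%, 63.4% and 65.3% of wild type. The log2 fold changes were -0.67, -0.58 and -0.58, with limma's adjusted p values of 0.00490, 0.0107 and 0.0112. The last of these calls ended without replicate 1 of the libraries labelled esa1Δ epl1Δ sds3Δ (-0.37, adjusted p 0.0534, over all alternatives from 0.000877 to 0.0534). Values per gene do not say which part of SDS3 the reads covered.

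Genes beside EPL1, ESA1 and SDS3 also changed. KTR7 (IX 200490 to 202043), which lies downstream of SDS3 on the same strand, rose from 19.3 ± 1.28 RPKM in wild type to 83.6 ± 0.687, 93.8 ± 5.02 and 83.9 ± 4.23 in the groups labelled epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ (SD, n = 3). Its log2 fold changes were 2.06, 2.22 and 2.06, with limma's adjusted p values of 8.71e-09, 2.07e-09 and 5.25e-09. CAB2 (IX 203556 to 204653), upstream of SDS3, fell (-1.23, -1.12 and -1.10) on the log2 scale. Beside EPL1, BUD27 (VI 90986 to 93376) rose by 1.71, 1.47 and 1.81, and BST1 (VI 84145 to 87234) fell by 0.42 in the libraries labelled esa1Δ sds3Δ (adjusted p 0.00874). Beside ESA1, DGA1 (XV 794076 to 795332) fell (-0.35, -0.59 and -0.59). PUS7 (XV 790211 to 792241) rose by 0.43 in the libraries labelled epl1Δ sds3Δ, with an adjusted p of 0.0387. That call ended without wild-type replicate 2 (0.0975) or 3 (0.172) and without replicate 1 (0.105) or 2 (0.107) of the libraries labelled epl1Δ sds3Δ, and over all alternatives its adjusted p ranged from 0.00126 to 0.419. In the libraries labelled esa1Δ sds3Δ PUS7 was not called (0.32, adjusted p 0.108), but was with the replicate number as a block (0.0332, over all alternatives from 0.00406 to 0.726). ESA1 itself rose by 0.47 in the libraries labelled epl1Δ sds3Δ (adjusted p 0.00689), but was not called with RPKM as deposited (0.23, adjusted p 0.229) or with a pseudocount of 0.1 (0.50, adjusted p 0.102). Over all alternatives its adjusted p ranged from 0.000787 to 0.229. HIS3 (XV 721946 to 722608), the marker of the esa1Δ allele, went from 13.7 ± 4.38 RPKM in wild type to 39.9 ± 1.39 and 40.9 ± 3.50 in the libraries labelled esa1Δ and 11.3 ± 2.01 in those labelled epl1Δ sds3Δ (SD, n = 3). The log2 fold changes of HIS3 were 1.51 and 1.54 (limma's adjusted p 1.14e-05 and 8.49e-06) in the former and -0.24 (0.251) in the latter. Of the other marker genes, ADE2 fell (-1.21, -1.99 and -1.59), CAN1 (-0.61, -0.79 and -0.85), LEU2 (-1.09, -0.47 and -1.07), and TRP1 (-1.11, -0.90 and -0.94). URA3 was not called in any of the 3 comparisons.

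**Figure D1:**
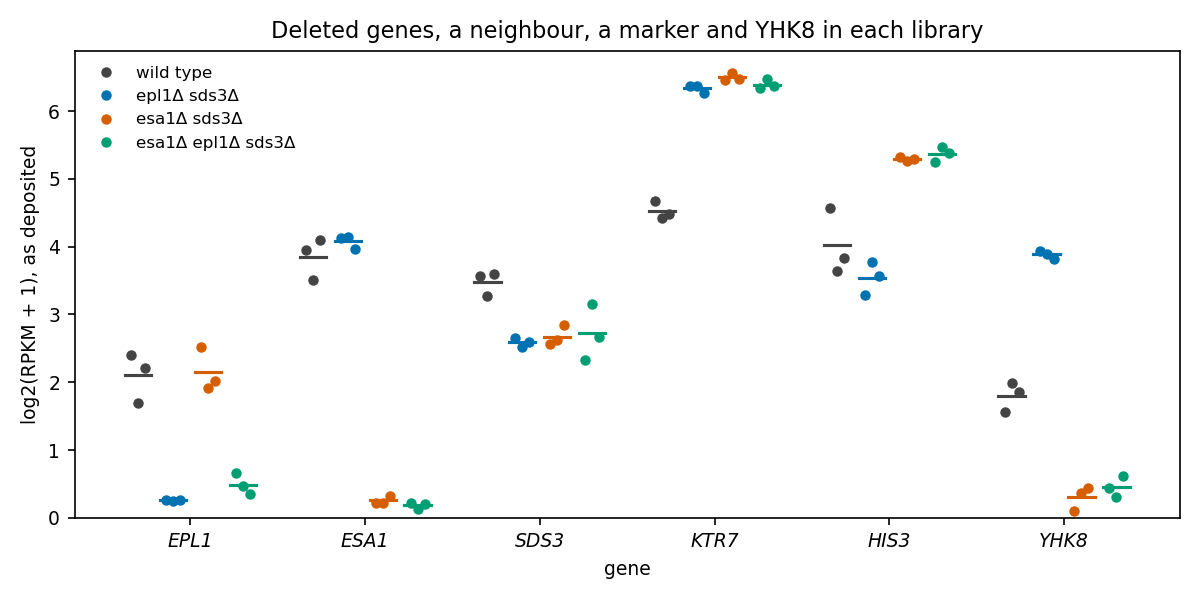
Level of EPL1, ESA1, SDS3, KTR7, HIS3 and YHK8 as log2(RPKM + 1), as deposited, in each of the 12 libraries (points), with group means as bars. ESA1 and EPL1 are near 0 where the label names them as deleted, whereas SDS3 is not.

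The libraries split by wild type against the rest. The first principal component held 68.5% of the variance and the second 6.41%. Wild-type libraries lay between -46.2 and -39.4 on the first component and the other 9 libraries between 13.0 and 16.4.

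The comparison of libraries labelled epl1Δ sds3Δ with wild type asked what differs where the label names EPL1 and SDS3 as deleted. The high-affinity phosphate transporter gene PHO89 (II 796798 to 798522) rose from 7.95 ± 2.36 to 123 ± 15.0 RPKM (SD, n = 3 each; log2 fold change 3.81, SE 0.160, limma's adjusted p 8.71e-09). The acid phosphatase gene PHO5 (II 429548 to 430951) rose from 142 ± 48.6 to 1261 ± 146 RPKM, and the meiotic regulator RIM4 (VIII 56649 to 58790) from 4.50 ± 0.965 to 41.2 ± 9.61. The zinc-regulated genes ADH4 (VII 15159 to 16307) and ZPS1 (XV 34658 to 35407) fell from 2859 ± 75.8 to 364 ± 47.2 RPKM and from 907 ± 205 to 88.6 ± 12.6. The guanine nucleotide synthesis gene IMD2 (VIII 554396 to 555967) fell from 47.0 ± 25.7 to 1.94 ± 0.518 RPKM, with a log2 fold change of -3.91 (SE 0.321, adjusted p 7.84e-07). Of 5956 genes tested, 3577 (60.1%) changed at an adjusted p under 0.05 in limma, 1792 up and 1785 down. The split was 1171 up and 2560 down with RPKM as deposited. At least 2-fold changes were seen in 898 genes, 550 up and 348 down, or 348 up and 638 down as deposited. The other genes named by the rule were CPP3, the mitochondrial lysine tRNA tK(UUU)Q, HSP26, ULI1, QDR2, GRE1 and HXT5, up by 2.84 to 3.49, and YOR387C, YIR042C, YPS6, NNR1, RRT13, YBR053C and YDR541C, which changed by -3.44 to -2.75. All 3 libraries of one group lay beyond all 3 of the other in 61.4% of genes, against 10% by chance.

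The comparison of libraries labelled esa1Δ sds3Δ with wild type asked what differs where the label names the catalytic subunit and SDS3 as deleted. The hydrophilin gene GRE1 (XVI 128632 to 129138) rose from 8.23 ± 2.02 to 107 ± 6.72 RPKM (SD, n = 3 each; log2 fold change 3.57, SE 0.156, limma's adjusted p 6.89e-09). The small heat shock protein gene HSP26 (II 382030 to 382674) rose from 76.0 ± 28.3 to 846 ± 131 RPKM, and NCA3 (X 193860 to 194873) from 1.85 ± 0.563 to 24.7 ± 1.40. PHO89 rose to 90.7 ± 2.28 RPKM. Among the genes that fell, IMD2 went to 1.74 ± 0.957 RPKM (-4.05), ZPS1 to 66.4 ± 14.7 (-3.75) and ADH4 to 331 ± 55.1 (-3.12, adjusted p 7.06e-09). In limma, 3554 genes (59.7%) changed, 1784 up and 1770 down, and 887 changed at least 2-fold, 538 up and 349 down. With RPKM as deposited the splits were 1162 up and 2562 down, and 339 up and 621 down for at least 2-fold. The other genes named were CPP3, tK(UUU)Q, PHO5, HXT5, SRX1 and YAL016C-A, up by 3.03 to 3.75, and YOR387C, YIR042C, YPS6, SRY1, CYB2, RRT13 and HPF1, which changed by -3.71 to -2.57. The groups separated fully in 63.1% of genes, against 10% by chance.

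Loss of both NuA4 genes was compared with wild type in the libraries labelled esa1Δ epl1Δ sds3Δ. PHO89 rose to 107 ± 14.2 RPKM (SD, n = 3; log2 fold change 3.61, SE 0.160, limma's adjusted p 1.11e-08). The mitochondrial tRNA tK(UUU)Q (MT 67061 to 67134) went from 0.541 ± 0.470 to 27.8 ± 6.85 RPKM, and CPP3 (IV 521314 to 521469) from 43.2 ± 15.7 to 592 ± 80.1. The wild-type value of tK(UUU)Q is near 0, and 1 read weighs more in so short an RNA than in a gene of 1 kb. Its fold change starts from this value in all 3 comparisons. IMD2 fell to 1.14 ± 0.337 RPKM (-4.37), ZPS1 to 60.1 ± 6.44 (-3.88) and ADH4 to 265.5 ± 32.1 (-3.43). The α-factor gene MF(ALPHA)2 (VII 344791 to 345153) fell from 150.1 ± 26.3 to 22.2 ± 1.93 RPKM (-2.69). In limma, 3539 genes (59.4%) changed, 1795 up and 1744 down, and 916 changed at least 2-fold, 552 up and 364 down. With RPKM as deposited the splits were 1251 up and 2354 down, and 399 up and 583 down. The other genes named were GRE1, YMR175W-A, HSP26, SRX1, PHO5, HXT5 and the mitochondrial tRNA tS(GCU)Q1, up by 3.09 to 3.47, and YOR387C, YIR042C, YPS6, RRT13, ADH5 and SRY1, which changed by -3.80 to -2.64. Full separation was seen in 64.1% of genes, against 10% by chance. Without the scaling factors the median log2 fold change of all genes was lower by 0.23, 0.23 and 0.19 in the comparisons of epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ.

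Genes for making ribosomes were higher in each of the 3 groups labelled as mutants. Of 97 tested genes for ribosome biogenesis and RNA polymerase I, 91 rose and 0 fell in the libraries labelled epl1Δ sds3Δ, 86 and 0 in those labelled esa1Δ sds3Δ, and 90 and 0 in those labelled esa1Δ epl1Δ sds3Δ. Adjusted over the list alone, 92, 88 and 91 rose and 0, 0 and 1 fell. The median log2 fold changes were 1.10, 1.01 and 1.05, with adjusted p values of 1.81e-17, 1.13e-15 and 2.16e-16 in limma's camera test. With an inter-gene correlation estimated from the residuals these calls ended, at adjusted p values of 0.595, 0.622 and 0.732. RPA14 (IV 769525 to 769938) rose by 2.04, 2.23 and 2.08 and RRN3 (XI 208247 to 210130) by 1.67, 1.63 and 1.77, while RLP24 rose by 1.86, 1.85 and 1.82. Of 137 cytosolic ribosomal protein genes, 116, 116 and 91 rose and 0 fell in any comparison (120, 120 and 93 rose adjusted over the list alone), with medians of 0.67, 0.65 and 0.52. Over the alternatives these medians ranged from 0.34 to 0.85, from 0.27 to 0.84 and from 0.27 to 0.71, the lowest of each under quantile normalization. The camera adjusted p values were 7.67e-16, 1.13e-15 and 3.49e-10, or 0.660, 0.622 and 0.732 with an estimated correlation. RPS17B (IV 1354829 to 1355553) rose by 1.90, 1.86 and 1.72 and RPL15B (XIII 509734 to 510348) by 1.17, 1.38 and 1.24. Many of these genes have near-identical copies, between which the reads are divided in a way the labels do not state. No list reached an adjusted p under 0.05 in any comparison when the correlation was estimated, although 4 lists in each comparison with wild type, and 1, 2 and 0 between mutant labels, had an unadjusted p under 0.05.

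**Figure D2:**
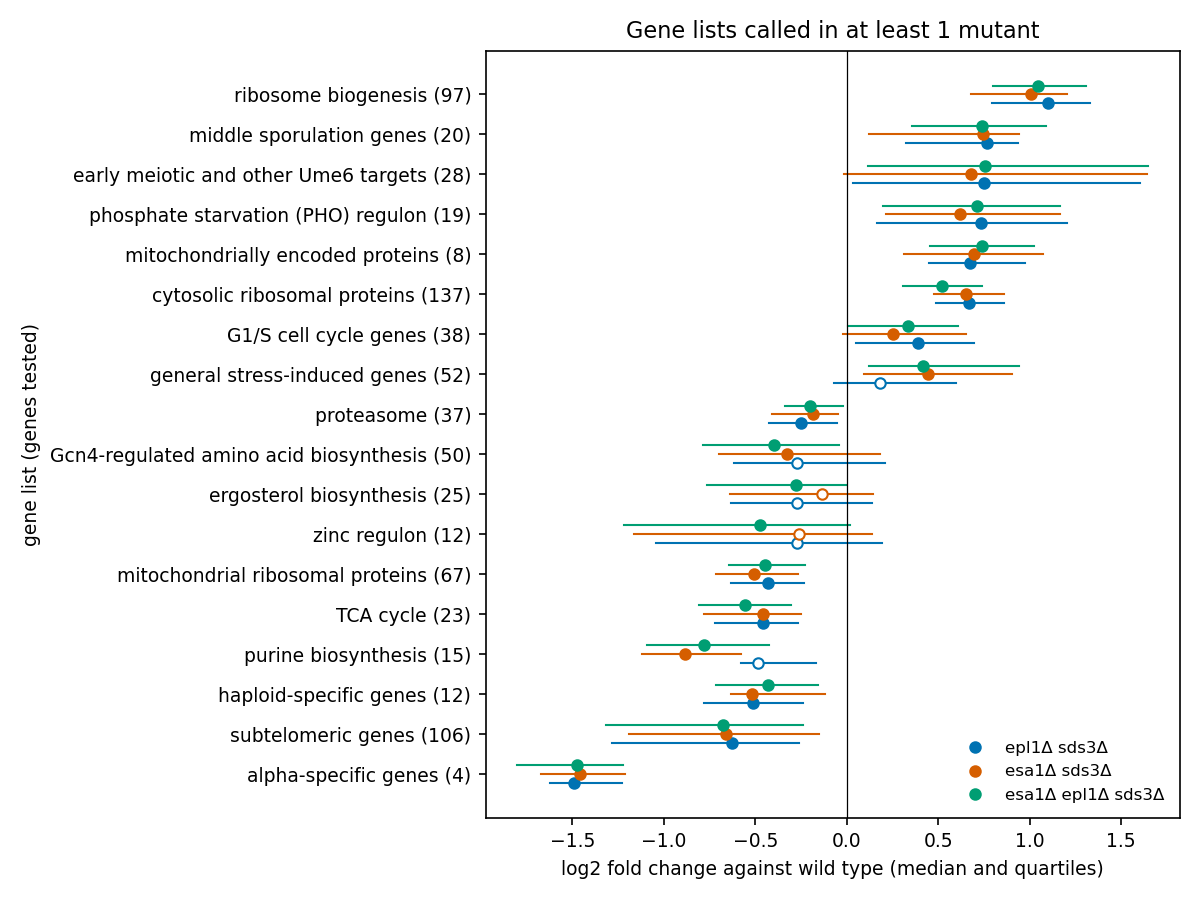
Median log2 fold change against wild type (points) with quartiles (bars) for the 18 gene lists past an adjusted p of 0.05 in at least 1 comparison with wild type in limma's camera test with the preset correlation; filled points passed and open points did not. None passed with an estimated correlation.

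Genes used in meiosis and sporulation were mostly higher in these haploid strains, and genes of the α mating type were lower. Of 28 tested early meiotic genes and other targets of the repressor Ume6, 16 rose and 4 fell in the libraries labelled epl1Δ sds3Δ, 17 and 3 in those labelled esa1Δ sds3Δ, and 19 and 3 in those labelled esa1Δ epl1Δ sds3Δ, with the same counts adjusted over the list alone. The medians were 0.75, 0.68 and 0.76 (camera adjusted p 0.00827, 0.00793 and 0.00195, or 0.473, 0.567 and 0.422 with an estimated correlation). Their size depended on the setting, from 0.25, 0.25 and 0.26 with a pseudocount of 5 to 1.64, 1.36 and 1.73 with voom. MND1 (VII 156543 to 157285) rose by 2.80, 2.59 and 2.84, and IME2 by 1.87, 1.69 and 1.91. PHR1 fell (-1.93, -1.80 and -1.73). The calls also ended when genes under a mean of 10 RPKM were left out, although the medians were 0.67, 0.86 and 0.86 (adjusted p 0.624, 0.493 and 0.430, the highest values over the alternatives with the preset correlation, the lowest being 0.000414, 0.000532 and 0.000102). Of 20 middle sporulation genes, 11, 11 and 12 rose and 3 fell in each comparison, the same as adjusted over the list alone, with medians of 0.77, 0.74 and 0.74 (0.0183, 0.0248 and 0.0172, or 0.250, 0.323 and 0.322 with an estimated correlation). The medians ranged from 0.25 to 1.26, from 0.23 to 1.10 and from 0.26 to 1.16 over the alternatives, the lowest of each with a pseudocount of 5. SPS100 (VIII 378219 to 379199) rose by 2.35, 2.89 and 2.38 and SPS4 fell (-0.99, -0.83 and -1.01). Under quantile normalization the middle sporulation calls ended for the labels epl1Δ sds3Δ (median 0.51, adjusted p 0.0616) and esa1Δ sds3Δ (0.50, 0.0547). Over the alternatives their adjusted p ranged from 0.00228 to 0.0616, from 0.00362 to 0.0547 and from 0.00273 to 0.0477. The 4 α-specific genes all fell in each comparison, over all genes and adjusted over the list alone, with medians of -1.49, -1.46 and -1.48 (0.00444, 0.00308 and 0.00238, or 0.388, 0.372 and 0.345 with an estimated correlation). Of 12 haploid-specific genes, 9, 7 and 8 fell and 0 rose, the same as adjusted over the list alone, with medians of -0.51, -0.52 and -0.43 (0.00827, 0.0134 and 0.0195, or 0.250, 0.323 and 0.345 with an estimated correlation). HO fell (-1.94, -2.34 and -2.05) and FAR1 (-1.06, -1.13 and -1.02). The haploid-specific calls ended at a minimum of 10 RPKM, with medians of -0.38, -0.18 and -0.26 (0.124, 0.211 and 0.316, with lowest values of 0.00439, 0.00719 and 0.0111 over the alternatives). HMRA1 of the silent cassette had a value above 0 in 1 of 12 libraries (0.312 RPKM), and HMRA2 and the other cassette and mating-type genes were listed at 0 in all 12. Since the α genes that these MATα strains express were among those at 0, the values do not read out silencing.

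Phosphate, stress and biosynthetic genes changed as well. Of 19 genes of the phosphate starvation regulon, 13, 14 and 14 rose and 2 fell in each of the comparisons labelled epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ, with the same counts adjusted over the list alone and medians of 0.73, 0.62 and 0.71. With RPKM as deposited the first 2 medians were 0.48 and 0.37. The camera adjusted p values were 0.000812, 0.00137 and 0.00199, or 0.595, 0.622 and 0.732 with an estimated correlation. PHM6 rose by 2.23, 2.12 and 2.13 and PHO84 by 1.35, 1.24 and 1.11, whereas PHO11 and PHO12, near-identical genes close to chromosome ends, fell. Of 52 general stress-induced genes, 14, 24 and 24 rose and 6, 2 and 2 fell (12, 23 and 22 rose and 2, 2 and 1 fell adjusted over the list alone), with medians of 0.18, 0.44 and 0.41. The stress list was not called for the label epl1Δ sds3Δ (0.112). It was called for the labels esa1Δ sds3Δ (0.00308) and esa1Δ epl1Δ sds3Δ (0.00254), but not without wild-type replicate 1 (0.0672 and 0.0639, the highest over the alternatives, from 3.03e-07 and 4.34e-07) or with an estimated correlation (0.759 and 0.734). The medians of these 2 labels were 0.27 and 0.21 without that library, 0.69 and 0.69 without wild-type replicate 3, and 0.19 and 0.21 as deposited. MOH1 rose by 1.99, 2.23 and 2.12 and GND2 by 1.79, 2.25 and 2.15. Of 50 amino acid biosynthesis genes regulated by Gcn4, 21, 25 and 30 fell and 9, 8 and 4 rose (23, 25 and 30 fell and 9, 8 and 4 rose adjusted over the list alone), with medians of -0.27, -0.33 and -0.40. The camera adjusted p was 0.0756 for the label epl1Δ sds3Δ, 0.0248 for esa1Δ sds3Δ and 0.000350 for esa1Δ epl1Δ sds3Δ. The Gcn4 call for esa1Δ sds3Δ ended without wild-type replicate 1 (median -0.18, adjusted p 0.0738, the highest of a range from 0.000926), and with an estimated correlation the called p values were 0.759 and 0.732. As deposited the 2 called medians were -0.58 and -0.60. GCV3 fell (-1.53, -1.72 and -1.70) and LYS1 (-1.48, -1.46 and -1.86), while SNO1 rose by 2.54, 1.90 and 1.85. Of 15 purine biosynthesis genes, 5, 11 and 11 fell and 1 rose in each comparison, the same as adjusted over the list alone, with medians of -0.48, -0.89 and -0.78. The purine list was called for esa1Δ sds3Δ (0.00308) and esa1Δ epl1Δ sds3Δ (0.00401), not for epl1Δ sds3Δ (0.109), and was at 0.653 and 0.732 with an estimated correlation. For the label esa1Δ epl1Δ sds3Δ alone, the zinc regulon (7 fell and 1 rose of 12, median -0.47, 0.0229) and ergosterol biosynthesis (13 fell and 3 rose of 25, median -0.28, 0.00930) were also called, each at 0.732 with an estimated correlation. The ergosterol median was -0.48 as deposited. In the other comparisons, 5 and 5 zinc genes fell and 3 and 2 rose (0.109 and 0.0672), and 12 and 12 ergosterol genes fell and 4 and 3 rose (0.0722 and 0.0639). Adjusted over the list alone, the zinc regulon had 7 falls and 2 rises for esa1Δ epl1Δ sds3Δ.

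Mitochondrial ribosome and tricarboxylic acid cycle genes were lower. Of 67 nuclear genes for mitochondrial ribosomal proteins, 47, 49 and 44 fell and 1, 0 and 2 rose in the order epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ (48, 51 and 44 fell and 1, 0 and 2 rose adjusted over the list alone). The medians were -0.43, -0.51 and -0.45 (camera adjusted p 1.61e-07, 1.58e-08 and 8.49e-08, or 0.473, 0.519 and 0.442 with an estimated correlation). The first median was -0.68 as deposited. MRPL35 fell (-1.10, -1.10 and -1.18) and MRPS9 (-0.90, -0.98 and -1.05). Of 23 tricarboxylic acid cycle genes, 13, 13 and 16 fell and 0, 1 and 1 rose (13, 14 and 16 fell and 0, 1 and 1 rose adjusted over the list alone), with medians of -0.46, -0.46 and -0.56, the first 2 at -0.71 and -0.71 as deposited. Their camera adjusted p values were 0.000812, 0.00137 and 0.000244, or 0.473, 0.599 and 0.442 with an estimated correlation. ACO1 fell (-1.33, -1.41 and -1.42) and CIT2 (-1.39, -1.33 and -1.43). Of the 8 protein genes of the mitochondrial genome, 5 rose and 0 fell in each comparison (5, 5 and 6 rose adjusted over the list alone), with medians of 0.68, 0.70 and 0.74. COX3 rose by 1.31, 1.40 and 1.19 and VAR1 by 1.35, 1.26 and 1.52, and ATP6 was not called. Their camera adjusted p values were 0.0407, 0.0389 and 0.0439, or 0.595, 0.622 and 0.732 with an estimated correlation. All 3 calls ended without wild-type replicate 1, with medians of 0.55, 0.57 and 0.63 (0.0732, 0.0672 and 0.0873). They also ended under quantile normalization, with medians of 0.38, 0.28 and 0.47 (0.0820, 0.0869 and 0.0792). At a minimum of 10 RPKM the calls ended for epl1Δ sds3Δ (median 0.70, adjusted p 0.0567) and esa1Δ epl1Δ sds3Δ (0.71, 0.0736). Single calls also ended without epl1Δ sds3Δ replicate 3 (median 0.55, adjusted p 0.0541), esa1Δ sds3Δ replicate 1 (0.70, 0.0779) or esa1Δ epl1Δ sds3Δ replicate 1 (0.68, 0.0639). Over the alternatives the adjusted p ranged from 0.0128 to 0.0820, from 0.0105 to 0.0869 and from 0.0172 to 0.0873.

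The G1/S cell cycle genes and the proteasome were nearer the threshold. Of 38 G1/S genes, 19, 16 and 19 rose and 4, 5 and 6 fell in the order epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ (the same numbers adjusted over the list alone, except 5 falls in the first), with medians of 0.39, 0.25 and 0.34. The camera adjusted p values were 0.0117, 0.0496 and 0.0300, or 0.712, 0.759 and 0.734 with an estimated correlation. As deposited the medians were 0.16, 0.0375 and 0.14. TOS4 rose by 1.08, 1.05 and 1.04 and CLN2 by 1.17, 1.03 and 1.18. The call for esa1Δ sds3Δ ended without wild-type replicate 3 (median 0.17, adjusted p 0.218) or its own replicate 1 (0.17, 0.0859). That for esa1Δ epl1Δ sds3Δ ended without wild-type replicate 3 (0.31, 0.155) or its own replicate 1 (0.31, 0.0512). At a minimum of 10 RPKM all 3 calls ended, although the medians were 0.44, 0.31 and 0.34 (0.0567, 0.109 and 0.161). Library weights ended those for esa1Δ sds3Δ (0.20, 0.0804) and esa1Δ epl1Δ sds3Δ (0.31, 0.0537), and the former also ended as deposited (0.0552), with a pseudocount of 5 (0.16, 0.0513) and in a fit of only the groups compared (0.0562). Over the alternatives the adjusted p ranged from 0.00587 to 0.0567, from 0.0259 to 0.218 and from 0.0152 to 0.161. Of 37 proteasome genes, 19, 16 and 16 fell and 1, 2 and 2 rose (17, 16 and 15 fell and 1, 2 and 2 rose adjusted over the list alone), with medians of -0.25, -0.18 and -0.20, or -0.51, -0.44 and -0.40 as deposited. PRE8 fell (-0.996, -0.801 and -0.905), while the proteasome regulator RPN4 rose by 1.36, 1.35 and 1.57. The proteasome values were 0.00827, 0.0240 and 0.0491, or 0.473, 0.622 and 0.732 with an estimated correlation. Over the alternatives they ranged from 0.00113 to 0.0820, from 0.00331 to 0.0739 and from 0.0101 to 0.484, the highest of each under quantile normalization, where the medians were -0.19, -0.15 and -0.0762. The last call also ended in 6 other settings (medians -0.20 to -0.19, adjusted p 0.0502 to 0.0883), and it ended without wild-type replicate 1 (0.0979) or 3 (0.0619) or without esa1Δ epl1Δ sds3Δ replicate 1 (0.0722) or 3 (0.0815).

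Genes near chromosome ends were lower in all 3 comparisons. Of 231 protein-coding genes that lie whole within 20 kb of an end, 106 were expressed enough to test. In the libraries labelled epl1Δ sds3Δ 71 fell and 11 rose, in those labelled esa1Δ sds3Δ 70 fell and 8 rose, and in those labelled esa1Δ epl1Δ sds3Δ 69 fell and 9 rose. Adjusted over the list alone, 73, 74 and 72 fell and 11, 8 and 9 rose. The medians were -0.63, -0.66 and -0.68 (camera adjusted p 1.48e-07, 7.04e-08 and 3.85e-08). With an estimated correlation the values were 0.0967, 0.0895 and 0.0770. The medians were -0.38, -0.40 and -0.44 with a pseudocount of 5, and -0.37, -0.43 and -0.42 with no filter on low values. With the limit at 40 kb they were -0.34, -0.38 and -0.36. FDC1 (IV 1512094 to 1513605) fell (-2.30, -2.38 and -2.47), and the subtelomeric ADH4 also belongs to the zinc regulon list. The difference was graded with distance. Of 32 genes within 10 kb, 28, 24 and 25 fell and 0 rose, with medians of -0.94, -0.86 and -1.01. Of 74 genes between 10 and 20 kb, 43, 46 and 44 fell and 11, 8 and 9 rose, with medians of -0.52, -0.58 and -0.61. Between 20 and 40 kb the medians over 241 genes were -0.17, -0.18 and -0.20, and beyond 80 kb they were -0.01, -0.01 and 0.00 over 4555 genes. Reads shared between near-identical subtelomeric genes may be divided or left out in these values.

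**Figure D3:**
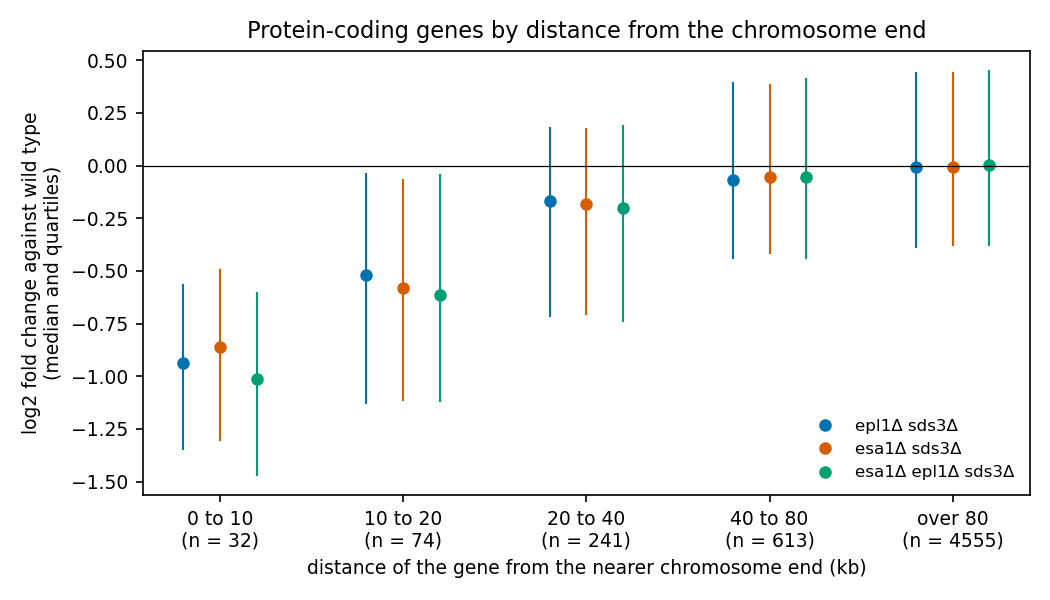
Median log2 fold change against wild type (points) with quartiles (bars) for protein-coding genes by distance from the nearest chromosome end, in kb, for the 3 mutant labels. The medians within 10 kb lie between -1.01 and -0.86 and those beyond 80 kb at about 0.

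Most snoRNAs were higher in each comparison with wild type. Of 75 snoRNAs, 63, 63 and 62 rose and 0 fell in the order epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ, with median log2 fold changes of 1.05, 1.01 and 1.05 in limma. With RPKM as deposited 61, 61 and 59 rose and 2, 3 and 1 fell, and under quantile normalization 57, 60 and 61 rose and 0, 3 and 4 fell. Of 12 mitochondrial tRNAs tested, 8 rose in each comparison, and both mitochondrial rRNAs rose in each. Of 104 nuclear tRNAs, 30, 24 and 19 rose and 1, 2 and 0 fell, and as deposited 26, 19 and 18 rose and 2, 4 and 1 fell. Single stable RNAs were picked out after their values had been seen. Of these, the telomerase RNA TLC1 fell (-1.11, -1.15 and -1.29) and the RNase MRP RNA NME1 rose by 1.14, 1.13 and 1.17. The spliceosomal snR6 rose by 1.06, 1.02 and 1.27, and snR14 by 1.25, 1.30 and 1.25. These directions held under each scaling tried. The direction of snR19 depended on the scaling, from 0.45, 0.28 and 0.34 in the main values to -0.24, -0.17 and -0.24 under quantile normalization (adjusted p 0.000869, 0.00632 and 0.000850). SCR1, at 0.38, 0.30 and 0.32, was not called as deposited (0.12, 0.04 and 0.12). The RNase P RNA RPR1, at 0.27, 0.15 and 0.23, was called in the libraries labelled epl1Δ sds3Δ alone (adjusted p 0.0403, 0.226 and 0.0727), and stood at -0.16, -0.24 and -0.10 under quantile normalization, where the second was called in the other direction (adjusted p 0.114, 0.0226 and 0.289).

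The other lists did not pass the camera test in any comparison with wild type, although single members changed. In the order epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ, 12, 12 and 12 of 25 glucose-repressed genes rose and 5, 5 and 5 fell (camera adjusted p 0.109, 0.105 and 0.0987), with ACS1 up by 2.65, 2.75 and 2.83 and SUC2 down (-2.16, -2.13 and -2.34). Of 32 cell wall integrity genes 16, 16 and 13 rose and 5, 5 and 6 fell (0.0540, 0.0672 and 0.103). For the label esa1Δ sds3Δ that list was called with the replicate number as a block (0.0428, over the alternatives with the preset correlation from 0.0243 to 0.522). Of 26 iron regulon genes 8, 7 and 7 rose and 7, 4 and 8 fell (0.684, 0.380 and 0.942). Of 20 heat shock chaperone genes 3, 3 and 3 rose and 11, 7 and 10 fell (0.112, 0.380 and 0.243), and of 31 G2/M genes 4, 4 and 5 rose and 13, 13 and 11 fell (0.106, 0.0905 and 0.227). Of 23 sulfate and methionine genes 11, 10 and 12 rose and 7, 6 and 6 fell (0.476, 0.480 and 0.494), and of 15 thiamine genes 7, 7 and 5 rose and 3, 5 and 4 fell (0.177, 0.212 and 0.494). Of 17 inositol-regulated phospholipid genes 1, 1 and 1 rose and 9, 7 and 8 fell (0.0649, 0.143 and 0.112), and of 21 glycolysis genes 5, 5 and 4 rose and 10, 8 and 10 fell (0.619, 0.930 and 0.375). Of 38 nuclear oxidative phosphorylation genes 7, 7 and 8 rose and 10, 8 and 10 fell (0.467, 0.788 and 0.375), and of 21 DNA damage response genes 9, 11 and 9 rose and 6, 6 and 5 fell (0.493, 0.296 and 0.494). Of 11 histone genes 2 rose and 5 fell in each comparison (0.558, 0.542 and 0.304), with HTB2 at -1.36, -1.38 and -1.73. Adjusted over the list alone these counts differed by at most 2 genes.

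Mating, adhesion and chromatin complex lists also stayed above the threshold. Of 6 a-specific genes 1, 2 and 2 rose and 1, 1 and 2 fell in the same order of labels (camera adjusted p 0.936, 0.930 and 0.984), with MFA1 up by 2.12, 1.66 and 1.72 and STE6 at -0.90, -0.75 and -0.83. AFB1 was not called in the libraries labelled esa1Δ sds3Δ (-0.33, adjusted p 0.0757), but was with the replicate number as a block (0.0490, over all alternatives from 0.000772 to 0.251). Of 11 pheromone-induced genes 3, 3 and 4 rose and 3, 2 and 3 fell (0.936, 0.907 and 0.944), and of 5 flocculation genes 1, 1 and 1 rose and 0, 1 and 0 fell (0.936, 0.901 and 0.944). Of 13 NuA4 subunit genes 2, 2 and 2 rose and 4, 5 and 5 fell (0.707, 0.476 and 0.475), which includes the deleted genes. Of 12 Rpd3L subunit genes 3, 4 and 7 rose and 4, 3 and 3 fell (0.989, 0.788 and 0.544), with UME6 up by 0.98, 0.96 and 0.98 and RPD3 at -0.62, -0.59 and -0.65. Of 16 other histone acetyltransferase genes 3, 3 and 6 rose and 3, 5 and 4 fell (0.936, 0.594 and 0.912), and of 20 other deacetylase genes 2, 3 and 3 rose and 3, 5 and 4 fell (0.558, 0.511 and 0.707). Of the 6 auxotrophic marker genes 0, 1 and 1 rose and 4, 4 and 4 fell (0.0579, 0.168 and 0.226). Adjusted over the list alone these counts differed by at most 3 genes. Median, mean and test differed in sign for the a-specific list in the libraries labelled epl1Δ sds3Δ, where the median was 0.04 and the test pointed down, and for the pheromone list in the others, where medians of -0.14 and -0.18 went with a test pointing up. They also differed for the thiamine, glycolysis, flocculation, NuA4, Rpd3L and other acetyltransferase lists in 1 or 2 comparisons each.

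The changes in the 3 comparisons with wild type were largely in the same genes. In limma, 2960 genes changed in 1 direction in all 3 mutant labels, 1498 up and 1462 down, and 420 up and 257 down were at least 2-fold in each. Independent lists of these sizes would share 162 up and 155 down, and 100 simulations of unchanged groups sharing simulated wild-type libraries gave 0 at most. With RPKM as deposited the numbers were 979 up and 2157 down. Of 4167 genes called in at least 1 comparison, 3 had opposite calls. The sign was the same in all 3 comparisons for 88.2% of genes, against 50.1% in the simulations. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.959 for epl1Δ sds3Δ with esa1Δ sds3Δ, 0.959 for epl1Δ sds3Δ with esa1Δ epl1Δ sds3Δ and 0.965 for esa1Δ sds3Δ with esa1Δ epl1Δ sds3Δ. Simulated unchanged groups gave 0.499, 0.502 and 0.501. The covariances were 0.521, 0.531 and 0.536 against 0.0151, 0.0152 and 0.0151 in the simulations, and the differences of 0.506, 0.515 and 0.521 estimate the shared effect. The simulations hold no changed genes. Part of the overlap and correlation among changed genes may therefore still come from the shared wild-type libraries, which are too few to split.

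**Figure D4:**
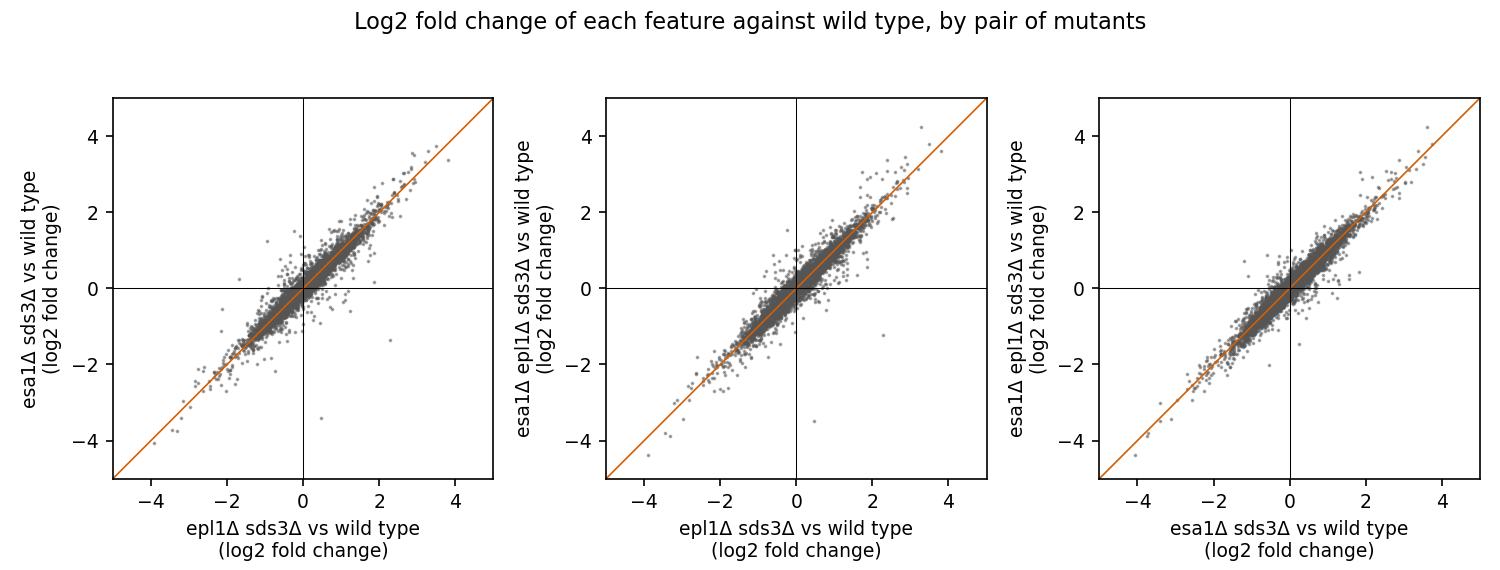
Log2 fold change against wild type of each tested gene in 1 mutant label against another, for the 3 pairs, with a line at equality. The points follow the line in each pair, with correlations of 0.959, 0.959 and 0.965 across genes, part of which comes from the shared wild-type libraries.

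Libraries labelled esa1Δ sds3Δ were compared with those labelled epl1Δ sds3Δ to ask whether loss of the catalytic subunit differs from loss of EPL1. The groups also differ in HIS3, the marker of the esa1Δ allele, whose effects cannot be told apart from those of the deletions. The predicted transporter gene YHK8 (VIII 204607 to 206151) was at 0.257 ± 0.165 against 14.4 ± 0.375 RPKM (SD, n = 3 each), with 1, 4 and 5 reads against 229, 180 and 164, and 40, 60 and 58 in wild type. ATG19 (XV 168727 to 169974) was at 31.7 ± 1.10 against 9.96 ± 1.66 RPKM (log2 fold change 1.59, SE 0.163, limma's adjusted p 0.000435). APD1 (II 545028 to 545978) was at 75.5 ± 7.08 against 36.3 ± 4.91 (1.04, 0.00193) and LEU1 (VII 476313 to 478652) at 171 ± 8.12 against 104 ± 6.19 (0.72, 0.00355). In all, 11 genes changed, 7 up and 4 down, of which ESA1, EPL1 and HIS3 mark the genotypes themselves, while 282 had an unadjusted p under 0.05. The calls of YHK8, ATG19, APD1 and LEU1 held without any one library. YSA1 (0.57), LEU2 (0.62), YBR137W (-0.96) and AQY3 (-1.08) were near the threshold, at 0.0226 to 0.0308. LEU2 lost its call without any one of the 6 libraries (0.118 to 0.252). YSA1 lost its call without replicate 1 or 2 of the label epl1Δ sds3Δ or any replicate of esa1Δ sds3Δ (0.0887 to 0.173). AQY3 lost it without replicate 2 or 3 of epl1Δ sds3Δ or any replicate of esa1Δ sds3Δ (0.104 to 0.177), and YBR137W without replicate 1 or 3 of epl1Δ sds3Δ or replicate 2 or 3 of esa1Δ sds3Δ (0.0594 to 0.173). The count was 7 without replicate 2 of the label esa1Δ sds3Δ. The upper ends were the highest adjusted p values over the alternatives, and the lowest were 0.00689, 0.00251, 0.00565 and 0.00802 for LEU2, YSA1, AQY3 and YBR137W. With all libraries, LEU2 lost its call without the variance trend (0.0506) and AQY3 with thinned reads (0.0787). YSA1 and YBR137W lost theirs in a fit of only the groups compared (0.0543 and 0.0588). The groups separated fully in 10.4% of genes, against 10% by chance. Purine biosynthesis was lower in the libraries labelled esa1Δ sds3Δ (median -0.48, camera adjusted p 2.93e-10, from 1.09e-17 to 1.47e-06 over the alternatives and 0.975 with an estimated correlation), with 0 members called over all genes and 7 lower when adjusted over the list alone.

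Libraries labelled esa1Δ epl1Δ sds3Δ differed by label from those labelled epl1Δ sds3Δ in the added loss of ESA1. They also differed in HIS3, the marker of the esa1Δ allele (log2 difference 1.78), and effects of marker and deletion cannot be told apart. YHK8 was at 0.381 ± 0.163 against 14.4 ± 0.375 RPKM (SD, n = 3 each) and APD1 at 73.1 ± 5.69 against 36.3 ± 4.91 (log2 fold change 0.99, limma's adjusted p 0.00474). In all, 8 genes changed, 2 up and 6 down, 2 of them ESA1 and HIS3, and 388 had an unadjusted p under 0.05. The calls of ESA1, HIS3, YHK8 and APD1 held without any one library. YBR137W (II 513044 to 513583) was lower (-1.04, 0.0172), AQY3 (VI 20847 to 22787) stood at -1.10 (0.0300), YMR315W (XIII 902800 to 903849) at -0.64 (0.0300) and TPO1 (XII 84804 to 86564) at -0.74 (0.0463). TPO1 (0.105 to 0.280) and YMR315W (0.0947 to 0.232) lost their calls without any one of the 6 libraries. AQY3 lost it without any but replicate 1 of epl1Δ sds3Δ (0.0689 to 0.201), and YBR137W without replicate 3 of epl1Δ sds3Δ or replicate 1 or 3 of esa1Δ epl1Δ sds3Δ (0.0765 to 0.105). The count was 4 without epl1Δ sds3Δ replicate 3 or esa1Δ epl1Δ sds3Δ replicate 1. It was 5 without esa1Δ epl1Δ sds3Δ replicate 2 or 3. Full separation was seen in 16.6% of genes, against 10% by chance. Gcn4-regulated amino acid biosynthesis was lower (median -0.22, camera adjusted p 9.95e-17) and so was purine biosynthesis (-0.46, 4.38e-09), while general stress-induced genes were higher (0.29, 2.27e-09). With an estimated correlation they were at 0.472, 0.472 and 0.794. The 3 calls held without any one library, but the stress median was 0.0905 without epl1Δ sds3Δ replicate 1 (adjusted p 0.0320).

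The last comparison, of libraries labelled esa1Δ epl1Δ sds3Δ with those labelled esa1Δ sds3Δ, asked what the loss of EPL1 adds once ESA1 is gone. ATG19 was at 10.9 ± 2.04 against 31.7 ± 1.10 RPKM (SD, n = 3 each; log2 fold change -1.47, limma's adjusted p 0.00200), and LEU1 at 94.2 ± 1.51 against 171 ± 8.12 (-0.85, 0.00200). With EPL1 itself (-1.71, 0.00450), these were the 3 genes called, and 377 had an unadjusted p under 0.05. The same number was called without any one library, but 10 were called with library weights and 6 in a fit of only the groups compared. LEU2 was at -0.60 and was not called (0.127). Full separation was seen in 20.3% of genes, against 10% by chance. Gcn4-regulated genes (median -0.17, camera adjusted p 1.11e-07, from 2.06e-09 to 0.00170 over the alternatives) and glycolysis genes (-0.17, 7.43e-05, from 3.91e-07 to 0.0170) were lower, and each was at 0.724 with an estimated correlation. Under quantile normalization the medians were -0.0833 and -0.0663, and the glycolysis median was -0.11 without esa1Δ epl1Δ sds3Δ replicate 1.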

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

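Of the tests in this part, the one of the scaling factors for the snoRNAs, both tests for SDS3 and the use of an interval in the snoRNA length test were chosen only after the result had been seen, as were thinning the reads and the choice of single stable RNAs.

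The snoRNAs stood about 1 log2 unit higher in all 3 mutant labels, on a scale where other genes had a median near 0. With RPKM as deposited the lowest of the 3 medians was 0.77, so the scaling factors are argued against as the whole source. After all libraries were thinned to one depth it was 1.00. RPKM is already divided by the library's reads, so thinning could move this median little. Both values are relative to the other RNAs, so neither bears on a change in total mRNA. Better recovery of short RNAs in the mutant libraries was expected to make the change fall with length. Among 75 snoRNAs of 78 to 1004 bases it showed no clear trend (Spearman rho 0.0570, permutation p 0.627, 100000 resamples, bootstrap 95% interval -0.164 to 0.295 from 2000 draws, Pearson r -0.149). By the rule set beforehand, a rho that was not negative goes against such recovery among the snoRNAs. The interval reaches negative values, so a weak fall with length is not excluded. Other stable RNAs leave recovery open. Of these, snR6, snR14 and snR7-L (112 to 214 bases) stood at 0.91 to 1.35. SCR1, snR19 and LSR1 (522 to 1175 bases) stood at 0.24 to 0.49, which goes with recovery by length. TLC1 (1301 bases) stood at -1.29 to -1.11, but 5515 protein-coding genes had medians of -0.03, -0.03 and -0.02. The fall of TLC1 therefore need not come from its length. NME1 and RPR1 differ little in length (340 and 369 bases) but stood at 1.14, 1.13 and 1.17 against 0.27, 0.15 and 0.23. As classes, 104 nuclear tRNAs had medians of 0.70, 0.68 and 0.56 and 12 mitochondrial tRNAs 2.01, 1.94 and 2.53. Most nuclear tRNAs were low, with 12 left at a minimum of 10 RPKM. The lengths of the tRNAs were not compared, so they do not decide on recovery. A change in snoRNA or ribosome production in these genotypes may be the source, but no test here tells it apart from recovery.

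The genes within 20 kb of chromosome ends stood lower in all 3 mutant labels. Low expression is argued against, because the list median lay below all of 10000 random lists matched on mean expression (percentile 0 in each comparison, lowest random medians -0.32, -0.30 and -0.28 for the labels epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ). Reads shared between near-identical copies are argued against as the whole source, because 65 of the 106 genes share no 50-base sequence with another place in the genome and the highest of their 3 medians was -0.54, although the other 41 were lower still (-0.84, -0.81 and -0.96). The highest of the 3 medians after thinning was -0.61. RPKM is already divided by the library's reads, so thinning could move this median little and does not decide on depth. A difference in chromosome ends between the strain lineages was not tested and stays open beside an effect of the genotypes, which may act on these regions.

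SDS3 kept 58.9%, 63.4% and 65.3% of its wild-type level in the libraries labelled epl1Δ sds3Δ, esa1Δ sds3Δ and esa1Δ epl1Δ sds3Δ. Wild-type cells in the cultures are argued against as the main source, because ESA1 stood at 1.74% of its wild-type level at most in the libraries labelled esa1Δ and EPL1 at 6.99% in those labelled epl1Δ sds3Δ and 14.2% in those labelled esa1Δ epl1Δ sds3Δ, although a small share of such cells is not excluded. KTR7 rose by 2.06 on the log2 scale at the least. Its own transcripts run away from SDS3, so they would not run into the gene. Whether transcripts that pass through SDS3 run on into KTR7, on the same strand, was not tested. CAB2, whose transcripts run towards SDS3, fell (-1.23, -1.12 and -1.10). Values per gene do not show where in SDS3 the reads lie, so transcripts that enter a part left in place, from CAB2 or a marker, and a label that is wrong for SDS3 cannot be told apart.

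Differences between mutant labels were picked out because the difference itself was tested. For esa1Δ sds3Δ against epl1Δ sds3Δ the log2 differences were -3.63 for YHK8, -1.08 for AQY3, -0.96 for YBR137W, 0.57 for YSA1, 0.62 for LEU2, 0.72 for LEU1, 1.04 for APD1 and 1.59 for ATG19. For esa1Δ epl1Δ sds3Δ against epl1Δ sds3Δ they were -3.49 for YHK8, -1.10 for AQY3, -1.04 for YBR137W, -0.74 for TPO1, -0.64 for YMR315W and 0.99 for APD1. For esa1Δ epl1Δ sds3Δ against esa1Δ sds3Δ they were -1.47 for ATG19 and -0.85 for LEU1. YSA1, LEU2, AQY3, YBR137W, TPO1 and YMR315W lost their limma calls without single libraries, with adjusted p values up to 0.173, 0.252, 0.201, 0.173, 0.280 and 0.232 and as low as 0.00251, 0.00689, 0.00538, 0.00457, 0.00538 and 0.00437 over their alternatives.

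List medians also differed between labels in limma's camera test with the preset correlation, and none of these calls held with an estimated one. For esa1Δ sds3Δ against epl1Δ sds3Δ the medians were -0.10 for ribosome biogenesis, 0.25 for general stress-induced genes, 0.10 for heat shock chaperones, -0.0616 for Gcn4-regulated genes, -0.48 for purine biosynthesis and 0.0708 for glycolysis. The estimated correlation gave an adjusted p of 0.975 for each. Without epl1Δ sds3Δ replicate 1, all of these but purine biosynthesis ended, at 0.510, 0.0536, 0.0700, 0.410 and 0.0592. Ribosome biogenesis also ended without esa1Δ sds3Δ replicate 3 (0.351). The Gcn4 call ended without epl1Δ sds3Δ replicate 3 (0.226) and esa1Δ sds3Δ replicate 1 (0.185) or 3 (0.0587), and the glycolysis call without epl1Δ sds3Δ replicate 2 (0.373) and esa1Δ sds3Δ replicate 2 (0.199) or 3 (0.461). Quantile normalization ended the calls for heat shock chaperones (median 0.0508, adjusted p 0.134) and glycolysis (0.0160, 0.606). Both the Gcn4 and the glycolysis call ended with no filter on low values (0.0518 each) and without the variance trend (0.0519 and 0.0507), the Gcn4 call with library weights (0.109) and thinned reads (0.0531), and the glycolysis call at a minimum of 10 RPKM (0.0695). Without epl1Δ sds3Δ replicates 1 and 3 in turn, the medians were -0.0337 and -0.18 for ribosome biogenesis and 0.0773 and 0.39 for stress-induced genes, and without esa1Δ sds3Δ replicate 3 they were -0.0468 and 0.14. The Gcn4 median was -0.0332 without epl1Δ sds3Δ replicate 1, -0.10 without replicate 2 and -0.0964 under quantile normalization. The glycolysis median was 0.04005 and 0.12 without epl1Δ sds3Δ replicates 2 and 3, and 0.14 and 0.0172 without esa1Δ sds3Δ replicates 1 and 3. Over the alternatives with the preset correlation, the adjusted p of these lists lay between 1.09e-17 and 0.606.

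For esa1Δ epl1Δ sds3Δ against epl1Δ sds3Δ the medians were -0.16 for cytosolic ribosomal proteins, 0.13 for early meiotic and Ume6 targets, 0.29 for stress-induced genes, -0.22 for Gcn4-regulated genes, -0.46 for purine and -0.17 for thiamine biosynthesis. They were -0.23 for the zinc regulon, -0.12 for ergosterol biosynthesis and 0.0846 for the proteasome. The Ume6 call ended without epl1Δ sds3Δ replicate 1 (0.0891), as deposited (0.0609), with no filter on low values (0.0557) and at a minimum of 10 RPKM (median 0.0653, adjusted p 0.728). The others held in every alternative with the preset correlation. Without epl1Δ sds3Δ replicate 1 the medians were 0.0905 for stress-induced genes and -0.12 for the zinc regulon. With a pseudocount of 5 they were 0.0676 for Ume6 targets and -0.0950 for thiamine biosynthesis. As deposited they were -0.0680 for ergosterol biosynthesis and 0.14 for the proteasome, and under quantile normalization -0.0744 for ribosomal proteins. Over the alternatives the values lay between 1.18e-24 and 0.728. The estimated correlation gave adjusted p values from 0.472 to 0.794. For esa1Δ epl1Δ sds3Δ against esa1Δ sds3Δ the medians were -0.14 for cytosolic ribosomal proteins, 0.0792 for Ume6 targets, -0.17 for Gcn4-regulated genes, -0.11 for thiamine biosynthesis, -0.11 for the iron regulon and -0.14 for the zinc regulon. They were -0.14 for ergosterol biosynthesis, -0.17 for glycolysis, -0.0544 for oxidative phosphorylation and 0.15 for other histone acetyltransferase genes. The estimated correlation gave from 0.724 to 0.916. Without esa1Δ sds3Δ replicate 2 the calls for Ume6 targets (0.0784), thiamine (0.162), zinc (0.185), ergosterol (0.0636) and acetyltransferase genes (0.0784) ended. Other single libraries ended the calls for Ume6 targets (esa1Δ sds3Δ replicate 1, 0.0509; esa1Δ epl1Δ sds3Δ replicate 3, 0.0645) and thiamine (esa1Δ epl1Δ sds3Δ replicate 3, 0.0908). Without esa1Δ sds3Δ replicate 3 the calls for zinc (0.115), oxidative phosphorylation (0.392) and acetyltransferase genes (0.0983) ended, and without esa1Δ epl1Δ sds3Δ replicate 1 they stood at 0.218, 0.256 and 0.207. Under quantile normalization the call for cytosolic ribosomal proteins ended (median -0.0202, adjusted p 0.413), as did those for Ume6 targets (0.0388, 0.0531), zinc (-0.0769, 0.260), ergosterol (-0.0380, 0.4998), oxidative phosphorylation (0.0158, 0.721) and acetyltransferase genes (0.11, 0.287). The medians for Gcn4-regulated genes and glycolysis were -0.0833 and -0.0663 there. At a minimum of 10 RPKM the calls ended for Ume6 targets (median -0.0820, adjusted p 0.825), thiamine (0.0991), iron (0.103), zinc (0.103), ergosterol (0.0633), oxidative phosphorylation (0.255) and acetyltransferase genes (median 0.0183, adjusted p 0.825). Oxidative phosphorylation also ended as deposited (0.0609) and with library weights (0.0619), and thiamine with thinned reads (0.0534). As deposited the medians were -0.0929 for ribosomal proteins, 0.12 for Ume6 targets, -0.0644 for thiamine, -0.0648 for iron, -0.0878 for zinc, -0.0931 for ergosterol and -0.00514 for oxidative phosphorylation. Voom gave 0.12 for Ume6 targets and -0.17 for thiamine, and a pseudocount of 5 gave 0.0443 for Ume6 targets. Without esa1Δ sds3Δ replicates 1, 2 and 3 in turn, oxidative phosphorylation had medians of -0.0979, -0.0906 and -0.0360, and it had -0.0874 without esa1Δ epl1Δ sds3Δ replicate 3. Ume6 targets had 0.12 and 0.16 without esa1Δ sds3Δ replicates 1 and 3, and zinc -0.23 and -0.0575 without replicates 1 and 2. Without esa1Δ epl1Δ sds3Δ replicate 1 the medians were 0.14 for Ume6 targets, -0.0829 for zinc and -0.11 for glycolysis. Thiamine had -0.0640 without esa1Δ sds3Δ replicate 2 and -0.18 without esa1Δ epl1Δ sds3Δ replicate 2. The adjusted p over the alternatives ranged from 4.01e-24, for ribosomal proteins, to 0.825. The median and the test, or the median and the mean, differed in sign between labels for several other lists that were not called.

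For each comparison, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes as were reported, and with 10 splits the share cannot be under 0.1. The real counts were 3577, 3554 and 3539 against wild type, where the highest count in another split was 0 in limma, with up to 537, 346 and 270 genes at an unadjusted p under 0.05. Every other split mixes wild-type and mutant libraries within a group, which widens the spread. The 0 calls there therefore say little about false calls. Between mutant labels the real counts were 11, 8 and 3, and the highest in another split was 1 in each. For esa1Δ sds3Δ against wild type, the replicate numbers were taken to pair the libraries, from the values alone. There, 3 of the 9 other splits part all 3 pairs as the real one does and 6 part 1 pair, and all gave 0 genes.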

How the results depend on the processing

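Voom on the recovered reads and thinning to one depth were chosen after the data had been seen.

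Against wild type, the counts of changed genes stayed within 1.5 times the reported counts under every alternative run. Without single libraries they ranged from 3256 to 3507 for the label epl1Δ sds3Δ, from 3189 to 3438 for esa1Δ sds3Δ and from 3132 to 3415 for esa1Δ epl1Δ sds3Δ, and the genes shared by all 3 from 2744 to 2904. Voom gave 3535, 3498 and 3565, and thinned reads gave 3373, 3331 and 3370. At a minimum of 10 RPKM, where 3812 genes were tested, the counts were 2490, 2470 and 2475. Genes changed at least 2-fold numbered 456, 448 and 486 with a pseudocount of 5, and 588 for epl1Δ sds3Δ at a minimum of 10 RPKM, as the construction of these settings shrinks low genes or removes them.

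Between mutant labels the counts are small. Without single libraries they ranged from 7 to 8 for esa1Δ sds3Δ against epl1Δ sds3Δ, from 4 to 6 for esa1Δ epl1Δ sds3Δ against epl1Δ sds3Δ and from 3 to 3 for esa1Δ epl1Δ sds3Δ against esa1Δ sds3Δ. In the same order they were 15, 12 and 10 with library weights and 14, 12 and 6 in a fit of only the groups compared. The second count went from 8 to 5 without the variance trend. The main fit pools the spread of all 12 libraries, wild type included, and its median SE was 0.130 in each of the 6 comparisons. A larger spread in wild type would therefore be understated in the comparisons with wild type. A chi-square of the recovered reads between replicates, per degree of freedom, was 34.0 to 53.8 in wild type, which was also sequenced deeper than most. It was 7.19 to 19.6 in the other groups, and 8.92 and 7.19 in the pairs with the deep replicate 3 of esa1Δ epl1Δ sds3Δ. The cause was not tested.

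The correlations of fold changes between labels, reported as 0.959, 0.959 and 0.965, were 0.930, 0.937 and 0.946 with a pseudocount of 0.1 and 0.978, 0.975 and 0.981 at a minimum of 10 RPKM. Without single libraries they ranged from 0.947 to 0.961, from 0.948 to 0.962 and from 0.955 to 0.968.

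With an inter-gene correlation estimated from the residuals, the adjusted p of all 47 list calls against wild type and all 25 between labels went above 0.05. With the preset correlation, 642 list results against wild type without single libraries were on the same side of the threshold, 17 calls were lost and 25 gained. A minimum of 10 RPKM lost 12 calls and gained 9, quantile normalization lost 8 and gained 8, and RPKM as deposited lost 1 and gained 9. Lists left with fewer than 4 genes at 10 RPKM gave no value. Of the list medians called, 2 changed sign, both for esa1Δ epl1Δ sds3Δ against esa1Δ sds3Δ. Oxidative phosphorylation went to 0.0158 under quantile normalization and the Ume6 targets to -0.0820 at a minimum of 10 RPKM. The cause was not tested. Of the named-gene results against wild type without single libraries, 3020 kept their side of the threshold, 16 lost and 6 gained a call.

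Outside the comparison of esa1Δ sds3Δ with wild type, the replicate numbers did not pair the libraries by the rule used. Of all 18 same-numbered pairs, 11 had deviations correlated above 0.1 (from -0.0984 to 0.289, and from -0.347 to 0.112 for different numbers), with each pair of replicates 3 at 0.155 or more. In 10 of 12 libraries the best match had the same number, a hint from the data rather than the design. With the replicate block the counts were 3731, 3717 and 3698 against wild type, 3115 for all 3, and 13, 9 and 3 between labels. The block lost 1 list call against wild type, the mitochondrially encoded proteins for esa1Δ epl1Δ sds3Δ (0.0525), and gained 2. For esa1Δ sds3Δ against wild type it gained the cell wall integrity list, PUS7 and AFB1 and changed no other list or named-gene call.

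Depth limits the low genes, since 1 read in 1 kb was worth 0.0688 to 0.124 RPKM and the wild-type libraries were deeper than most others.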
